A study of Ovis aries with 8 samples.

How the data were processed

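Poly(A)-selected RNA from 8 cultures of ovine skeletal muscle satellite cells was sequenced on an Illumina NovaSeq. Satellite cells are the resident stem cells of skeletal muscle. Per the labels' protocols, the cells were primary cells of Suffolk x Texel genotype, were transfected with a lipid reagent at 60% confluence, and were harvested 4 days later. The miR-127 mimic was given at 100 nM and the antagomiR against miR-22-3p at 500 nM. A mimic is a double-stranded RNA that adds microRNA activity, and an antagomiR is a modified antisense strand that binds and blocks a microRNA. The labels do not give the sequence or the concentration of the 2 control oligonucleotides, nor the arm (3p or 5p) of the miR-127 mimic.

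The authors deposited 1 table of raw read counts per gene, with 20921 gene rows and 8 columns, 1 column per sample and no pooling. The counts were not normalized: they are whole numbers and sum to a different total in each column. The submitters' processing notes list FastQC 0.11.8, Trim Galore 0.6.5, RSEM 1.3.3, Subread, featureCounts 2.0.2 and edgeR 3.34.1, with no role or order. The genome build, the annotation release, the strand setting and the treatment of multi-mapping reads and read pairs are not given in the sources used here. Of the counts from 1 to 100 in a library, between 11.9% and 15.6% were odd, where about 50% would be odd if each count stood for 1 independent read. Sets of genes also had near-identical counts in every library (80 genes in 31 sets, within 2% in each of the 8 libraries, among genes with at least 1000 counts in all). Both facts bear on sampling error: intervals and floors based on counts cover counting error only and treat each count as independent.

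All 20921 identifiers are Ensembl sheep gene IDs. The table of RefSeq sheep genes used for names pairs none of them with a symbol (0 matched), and no genome was used here. Genes are therefore given by ID, without symbol, position or function, and at most 2 IDs are printed per direction in each comparison. The gene lists and the microRNA seed-site tests that had been planned need symbols and 3' UTR sequences, so they were not run. The column names matched the sample descriptions, except that both miR-127 mimic samples carry the same description. Those 2 columns were matched by the experiment number in the sample titles.

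Groups were taken from the sample titles. There were 4 groups of 2 libraries, and nothing in the labels says whether the 2 came from separate animals, so p-values measure the spread between these samples, which may be technical. Before the data were examined, the tests, the alternatives and the rule for named genes were fixed. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with edgeR's default expression filter (a minimum count of 10 and a minimum total of 15), which left 16353 genes; 2981 of the others had no count in any library. Libraries were scaled with TMM factors, which ran from 0.915 to 1.11. The main test was edgeR's quasi-likelihood F test in 1 model with a mean for each group, fitted to all 8 libraries. This model leaves 4 residual degrees of freedom, to which edgeR added 6.29 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p of 0.05 or less. The standard error (SE) of a log2 fold change is the fold change divided by the square root of its F statistic. It follows from the test, and for a gene with counts near 0 it does not measure the precision of the fold change. Levels are given as CPM (counts scaled to a common library total, with TMM factors), computed here from the counts.

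The tests were 2-sided. The contrasts were each treated group against its own control, the 2 control groups against each other, and the difference between the 2 treatment effects. A contrast of all mimic-type against all antagomiR-type libraries was added after the data were seen. The rule for named genes took, in each direction, the genes with the largest fold change among those called or, where fewer than 5 were called, those with the smallest p. They also had to have a mean level of at least 2 log2 CPM and no overlap between the 2 groups. The rule did not say how the mean is formed, and edgeR's average log2 CPM over the libraries compared, which adds a prior count, was used. By the log2 of the mean CPM, ENSOARG00000001538 falls short of the rule (1.98, against 2.00 by edgeR's average). By the mean of log2 CPM with a prior count of 2, so do ENSOARG00000001538 (1.75), ENSOARG00000020312 (1.99) and, in the mimic comparison, ENSOARG00000018571 (1.41). The rule's requirement of a symbol, and its list of genes always to be named, could not be applied.

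Other settings fixed before the data were examined were RLE size factors, DESeq2 1.42.0, no expression filter, a stricter filter (1 CPM in at least 4 libraries), the replicate number as a block, only the libraries compared, other thresholds, and leaving out each library. Halved counts, 1 gene per matching set, scaling by library totals, the newer quasi-likelihood fit, a likelihood-ratio test, a range of scaling factors for the control mimic libraries, a separate fit of the treated groups and the other readings of the mean level were added after the data were seen. The replicate numbers were not taken as pairs. The labels do not say that a number marks a shared day or animal, and the deviations of same-numbered libraries from their group means correlated at 0.17 across genes in the antagomiR pair of groups and at 0.04 in the mimic pair.

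The main test was tested on simulated counts with the means, dispersions and library sizes of these data and 200 changed genes among 16353. In the simulated antagomiR comparison, 62.7% of 67 genes changed 2-fold and 83.3% of 66 genes changed 4-fold were called, against 34.3% of 67 genes changed 1.5-fold. The same shares in the simulated mimic comparison were 68.7%, 86.4% and 17.9%. In the simulated comparison of the controls they were 65.7%, 86.4% and 26.9%. Unchanged genes gave 12 of 132, 10 of 125 and 8 of 127 calls in these 3 simulations. The search for matching genes found 50 of 50 planted pairs and no other.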

Results

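The series measured gene expression in ovine satellite cells 4 days after transfection with a miR-127 mimic, an antagomiR against miR-22-3p, or the control oligonucleotide of either type, each in 2 libraries. Its title gives the purpose as examining how microRNA mimics and inhibitors affect satellite cell proliferation in vitro. The libraries held from 26637300 to 35843926 counts, and between 16677 and 16999 genes had at least 1 count. The 10 most abundant genes took between 8.41% and 10.9% of the counts of a library. Log2 CPM values of the 2 libraries of a group correlated at r = 0.972 to 0.979 across genes, and those of libraries from different groups at r = 0.964 to 0.982, so that replicates were not always closer to each other than to other groups. No 2 libraries of a group looked like copies of 1 library, since chi-square per degree of freedom between them was 9.38 to 31.5, where sampling noise of independent reads gives 1. Between the 2 antagomiR-type groups this measure was 18.2 and 14.7 for same-numbered libraries and 29.0 and 23.4 for differently numbered ones. Between the 2 mimic-type groups the same values were 27.4 and 14.0 against 14.7 and 38.5. On the first principal component (26.2% of the variance), the 4 libraries of the antagomiR type lay between -28.8 and -18.9 and the 4 of the mimic type between 9.51 and 42.0. Within each type the treated libraries also lay higher on it than their controls. The antagomiR-22-3p libraries lay at -18.9 and -20.6, and the control antagomiR at -28.8 and -27.0. The miR-127 mimic libraries lay at 42.0 and 32.7, and the control mimic at 11.1 and 9.51.

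The first comparison asked which transcripts respond when miR-22-3p is inhibited. No gene was called between the antagomiR-22-3p libraries and the control antagomiR libraries by edgeR's quasi-likelihood test (0 of 16353 genes, n = 2 per group). ENSOARG00000004659 came nearest in this test. Its level was 29.7 ± 7.34 CPM in the control antagomiR and 9.17 ± 0.88 CPM in the antagomiR-22-3p libraries (SD, n = 2), a log2 fold change of -1.69 (SE 0.20) with an adjusted p of 0.088 by edgeR. The adjusted p rested on single libraries: it was 0.039 without control antagomiR replicate 1, 0.42 without control antagomiR replicate 2, 0.76 without antagomiR-22-3p replicate 1 and 0.31 without antagomiR-22-3p replicate 2, and 0.41 with only the 4 libraries compared. In the control mimic and miR-127 mimic libraries the same gene stood at 13.9 ± 1.87 and 12.5 ± 1.31 CPM, so that the control antagomiR libraries held the highest level of the 4 groups.

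The other genes named by the rule had smaller differences. ENSOARG00000000021 stood at 35.5 ± 3.19 CPM in the control and 53.2 ± 0.75 CPM after antagomiR-22-3p, a log2 fold change of 0.58 (SE 0.10, adjusted p = 0.65 by edgeR). ENSOARG00000004311 stood at 43.6 ± 3.27 and 61.6 ± 1.78 CPM, a log2 fold change of 0.50 (SE 0.09, adjusted p = 0.65 by edgeR). A second gene had counts within 2% of those of ENSOARG00000004311 in each library, so these reads cannot be given to 1 of the 2 genes. ENSOARG00000016023 stood at 44.8 ± 3.53 and 32.9 ± 1.78 CPM, a log2 fold change of -0.44 (SE 0.10, adjusted p = 0.97 by edgeR). In the control mimic and miR-127 mimic libraries, ENSOARG00000000021 stood at 45.9 and 55.0 CPM and ENSOARG00000004311 at 95.6 and 104 CPM. The control antagomiR libraries thus held the lowest level of both genes among the 4 groups. ENSOARG00000016023 stood at 42.8 and 46.9 CPM there, so its lowest level was in the antagomiR-22-3p libraries.

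At an unadjusted p under 0.05, 824 genes differed between antagomiR-22-3p and its control, where 818 are expected by chance, and 650 of them were higher and 174 lower after the antagomiR. With RLE size factors the same count was 694 higher and 150 lower. With library totals, which moved the median log2 fold change of all genes from 0.0019 to -0.071, it was 395 higher and 387 lower. The 824 genes of the main test were not spread evenly by abundance. They included 354 of the 4088 most abundant genes tested and 128 of the 4089 least abundant. In between, they included 196 of the 4088 more abundant genes and 146 of the 4088 less abundant ones. By chance these numbers would be about equal, so the total near 818 hides an excess among the most abundant genes. Its cause was not tested. The 2 groups did not overlap for 35.9% of genes, against 33.3% by chance for 2 libraries against 2. DESeq2 called 58 genes, of which 57 were higher, with a median of 1.34-fold among those. Its own filter left 15218 of the 16353 genes without an adjusted p, ENSOARG00000004659 among them, so these calls came from the few genes that remained. A likelihood-ratio test in edgeR called 20 genes, of which 1 was among the 58. The quasi-likelihood test recovered 62.7% of genes changed 2-fold in simulated libraries like these, so smaller or rarer changes were not excluded.

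**Figure D1:**
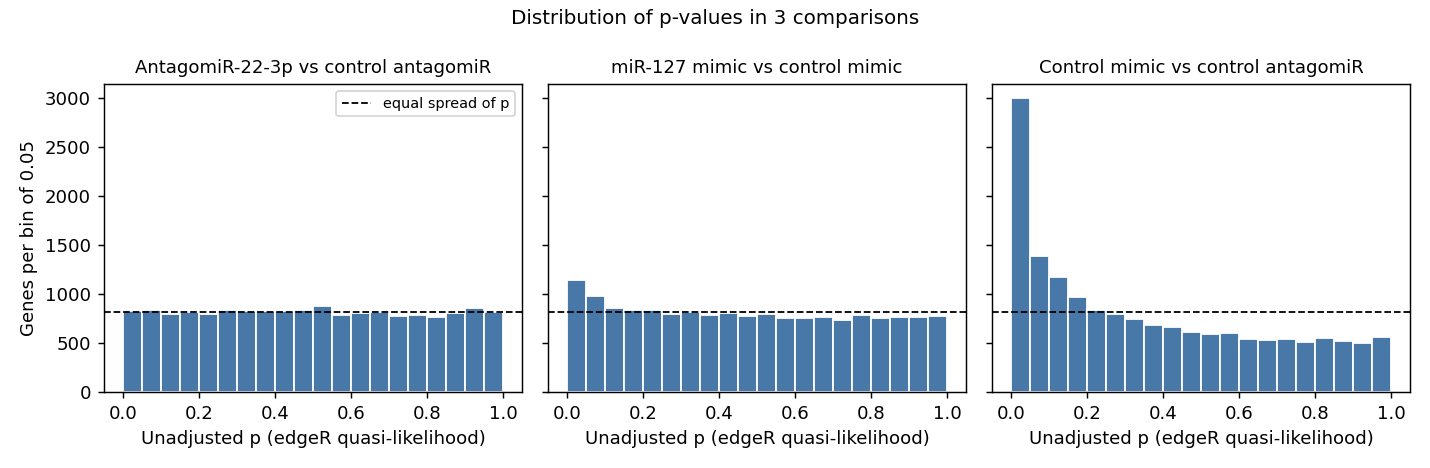
Number of genes (vertical axis, per bin of 0.05) by unadjusted p from edgeR's quasi-likelihood test (horizontal axis) for the 3 pairwise comparisons; the dashed line is the number per bin if p were spread evenly. The first bin holds 824 genes for antagomiR-22-3p, 1143 for the miR-127 mimic and 2997 for the control mimic against the control antagomiR.

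The second comparison asked which transcripts respond when miR-127 is added. No gene was called between the miR-127 mimic and the control mimic libraries (0 of 16353 genes, edgeR's quasi-likelihood test, n = 2 per group), but 4 genes had an adjusted p of 0.1 or less, all with lower levels after the mimic. The lowest adjusted p of a named gene was that of ENSOARG00000018571, which stood at 22.9 ± 1.63 CPM in the control mimic and 0.70 ± 0.99 CPM in the miR-127 mimic libraries (SD, n = 2), a log2 fold change of -5.16 (SE 0.62, adjusted p = 0.060 by edgeR). The adjusted p moved both ways when 1 library was left out, which leaves a group of 1 library. It was 0.27 without control mimic replicate 1 and 0.55 without control mimic replicate 2 (log2 fold change -5.23 and -5.09), 0.017 without miR-127 mimic replicate 1 (log2 fold change -4.02), and 0.0010 without miR-127 mimic replicate 2, where the library left has no count and the fold cannot be measured. Its counts were 578 and 782 in the 2 control mimic libraries, and 0 and 36 in the 2 miR-127 mimic libraries. The count of 0 allows up to 3 counts, or 0.0907 CPM of that library's unscaled total. With such counts the SE of 0.62 does not measure the precision of the fold. ENSOARG00000019419 stood at 55.9 ± 8.76 CPM in the control and 26.8 ± 4.67 CPM after the mimic, a log2 fold change of -1.07 (SE 0.14, adjusted p = 0.075 by edgeR). Its adjusted p was 0.92 without control mimic replicate 2, 0.27 without control mimic replicate 1, 0.42 without miR-127 mimic replicate 1 and 0.017 without miR-127 mimic replicate 2. In the other direction, ENSOARG00000020058 stood at 1360 ± 131 and 2532 ± 536 CPM, a log2 fold change of 0.90 (SE 0.14, adjusted p = 0.22 by edgeR). Without miR-127 mimic replicate 2 its adjusted p was 0.0055, and without control mimic replicate 1 or 2 it was 0.90 or 0.98. ENSOARG00000007234 stood at 22.8 ± 1.11 and 42.6 ± 9.93 CPM, a log2 fold change of 0.90 (SE 0.15, adjusted p = 0.32 by edgeR), and was called under no setting that left out 1 library. DESeq2 called ENSOARG00000019419, ENSOARG00000020058 and ENSOARG00000007234, but not ENSOARG00000018571 (adjusted p = 0.22).

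At an unadjusted p under 0.05, 1143 genes differed between the miR-127 mimic and its control, against 818 expected by chance, of which 558 were higher and 585 lower after the mimic. With RLE size factors, 587 were higher and 563 lower, and with library totals, 430 were higher and 722 lower. The groups did not overlap for 35.9% of genes, against 33.3% by chance. DESeq2 called 43 genes, 21 higher with a median of 1.75-fold and 22 lower with a median of 2.14-fold, and 40 of these 43 were among the 92 genes of edgeR's likelihood-ratio test. The 2 miR-127 mimic libraries stood apart: their correlation was the lowest within a group (r = 0.972), their chi-square per degree of freedom the highest (31.5), and on the second principal component (17.5% of the variance) replicate 1 lay at 42.0 and replicate 2 at -22.4. Without miR-127 mimic replicate 2, the quasi-likelihood test called 60 genes, 12 higher and 48 lower, with the lone remaining library assumed to vary like the other groups. Without miR-127 mimic replicate 1 it called 1 gene.

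**Figure D2:**
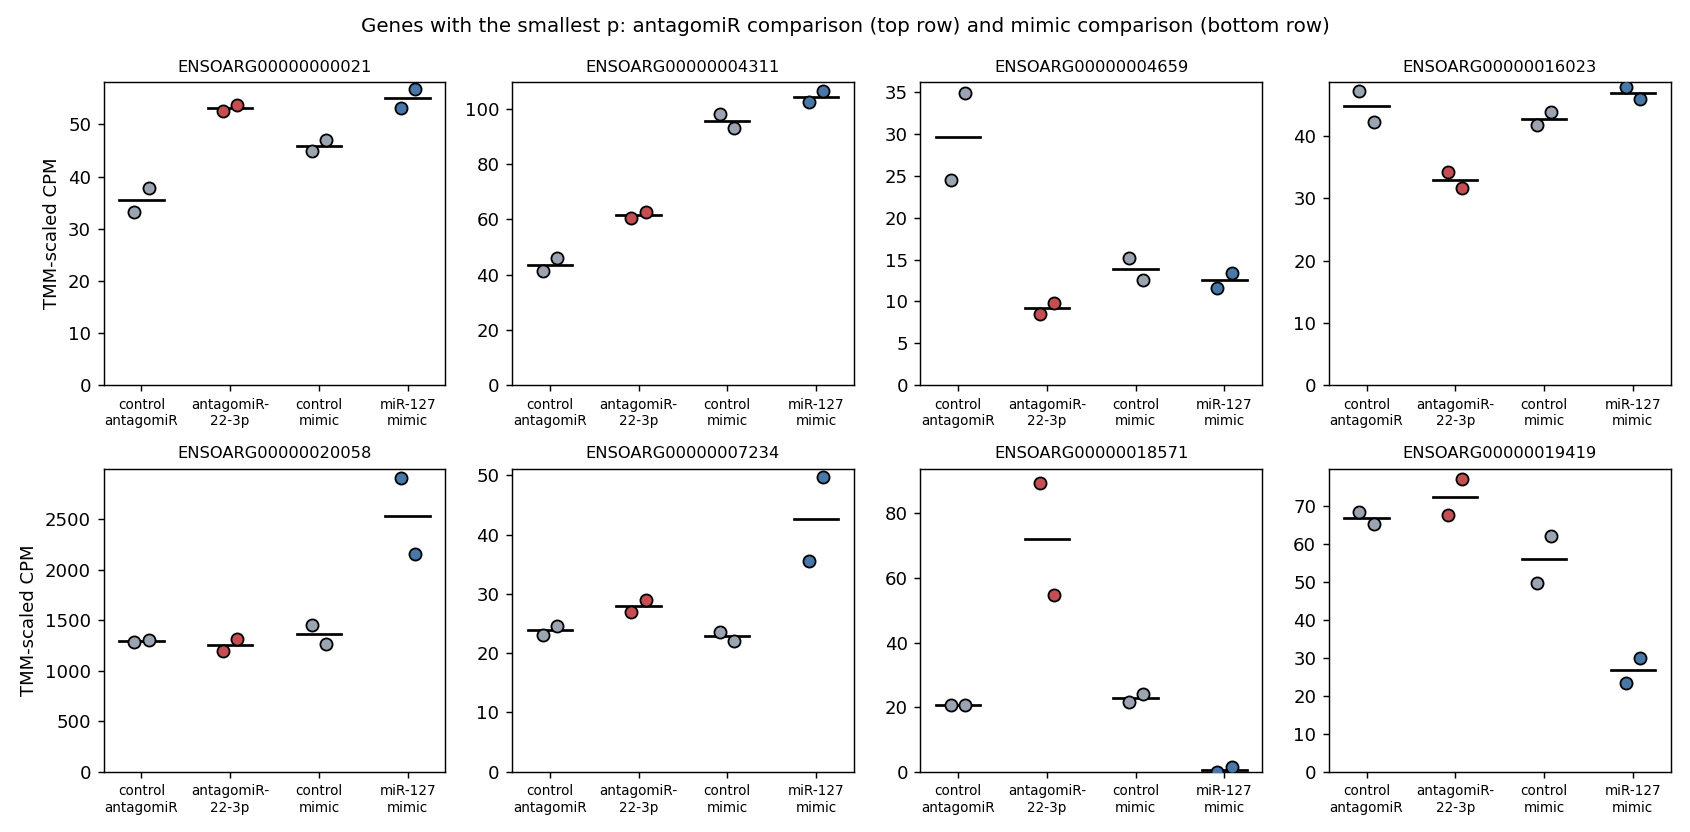
TMM-scaled CPM (vertical axes, from 0) of the 8 genes named in the treatment comparisons, by group; points are single libraries (2 per group) and bars are group means. The top row holds the genes of the antagomiR comparison and the bottom row those of the mimic comparison, where ENSOARG00000018571 lay at 0 and 1.41 CPM in the miR-127 mimic libraries and at 21.8 and 24.1 CPM in the control mimic libraries.

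The difference between the 2 treatment effects was then tested in itself. One gene, ENSOARG00000018571, was called: its log2 fold change was higher in the antagomiR comparison than in the mimic comparison by 6.96 (SE 0.75, adjusted p = 0.043 by edgeR's quasi-likelihood test). It stood at 20.7 ± 0.11 CPM in the control antagomiR and 72.0 ± 24.4 CPM in the antagomiR-22-3p libraries. The call did not hold under DESeq2 (adjusted p = 0.42) or without control mimic replicate 2 (adjusted p = 0.65 by edgeR), and it was also lost without control mimic replicate 1, either control antagomiR library or antagomiR-22-3p replicate 1. The difference stayed positive under all settings run, from 5.82 to 7.28 where the miR-127 mimic libraries used held a count; without miR-127 mimic replicate 2 they held none, and its size cannot be measured. Each fit without 1 library leaves a group of 1, with its spread taken from the other groups. The other genes named by the rule were not called. By the quasi-likelihood test the difference was 1.65 (adjusted p = 0.099) for ENSOARG00000000794, -1.54 (0.71) for ENSOARG00000004659 and -1.30 (0.75) for ENSOARG00000021116. DESeq2 called all of them (adjusted p from 1.4e-06 to 0.021). ENSOARG00000000794 stood at 20.8 and 29.5 CPM in the control antagomiR and antagomiR-22-3p libraries. In the control mimic and miR-127 mimic libraries it stood at 17.1 and 7.74 CPM. At an unadjusted p under 0.05 by the quasi-likelihood test, the effects differed for 987 genes, where 818 are expected by chance. Across the 16353 genes, the log2 fold changes of the 2 treatments, which share no library, correlated at r = -0.018 and rho = -0.028. Genes are not independent replicates, so no p is given.

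The control mimic and control antagomiR libraries were compared as a background for both treatments. Between them 722 genes were called (edgeR's quasi-likelihood test, n = 2 per group), 663 higher and 59 lower in the control mimic, with a median of 1.62-fold among the higher and 1.52-fold among the lower. ENSOARG00000001538 rose from 1.77 ± 0.18 CPM in the control antagomiR to 6.14 ± 0.80 CPM in the control mimic, a log2 fold change of 1.79 (SE 0.31, adjusted p = 0.012 by edgeR). ENSOARG00000019072 rose from 5.70 ± 0.85 to 15.1 ± 0.65 CPM (log2 fold change 1.40, SE 0.21, adjusted p = 0.0056 by edgeR). ENSOARG00000018144 fell from 43.4 ± 1.19 to 14.7 ± 1.66 CPM (log2 fold change -1.57, SE 0.19, adjusted p = 0.0032 by edgeR), and ENSOARG00000020312 fell from 6.93 ± 0.51 to 2.20 ± 0.45 CPM (log2 fold change -1.65, SE 0.34, adjusted p = 0.023 by edgeR). Leaving out 1 of the 4 control libraries lost some of these calls, but it also leaves a group of 1 library. The log2 fold changes then kept their sign. They ran from 1.65 to 1.92 for ENSOARG00000001538, 1.25 to 1.57 for ENSOARG00000019072, -1.46 to -1.69 for ENSOARG00000018144 and -1.46 to -1.88 for ENSOARG00000020312. ENSOARG00000001538 and ENSOARG00000020312 were lost without any 1 of the 4 (adjusted p from 0.068 to 0.090 and from 0.072 to 0.17), ENSOARG00000019072 without control mimic replicate 1 (0.055) or 2 (0.080), and ENSOARG00000018144 without control mimic replicate 2 (0.067). All 4 were called by DESeq2.

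The called genes were mostly abundant ones. Of the 722, 467 were among the 4088 most abundant genes tested and 16 among the 4089 least abundant. The median SE was 0.094 in the former and 0.55 in the latter, so equal differences were harder to call among the least abundant. These counts therefore do not show that the difference was larger in abundant genes. The groups did not overlap for 52.8% of genes, against 33.3% by chance. RLE size factors gave 725 calls, 666 higher and 59 lower. Library totals, which moved the median log2 fold change of all genes from -0.0091 to -0.17, gave 960 calls, 457 higher and 503 lower. The count fell when any 1 of the 4 control libraries was left out, which leaves a group of 1 library. It was 151 without control antagomiR replicate 1, 336 without control antagomiR replicate 2, 159 without control mimic replicate 1 and 2 without control mimic replicate 2.

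A contrast between the 2 oligonucleotide types was also available in the treated cells, which share no library with the controls. Unlike that between the controls, it also holds any effects of the miR-127 mimic and of antagomiR-22-3p. An average of the 2 contrasts holds them too. Between the miR-127 mimic and antagomiR-22-3p libraries, 692 genes were called, 501 higher and 191 lower in the mimic. Of the 722 genes called between the controls, 97.5% had the same sign between the treated groups, against 65.6% of all genes tested, in the model of all 8 libraries. With each contrast fitted in its own 4 libraries, 1052 genes were called between the controls, of which 94.1% had the same sign between the treated groups. In both contrasts, 317 genes were called in the same direction, 295 higher and 22 lower in the mimic type, where 21 would be shared by independent lists. The 2 lists are not independent, because 1 model gave both contrasts the same estimate of spread for each gene. The 21 is therefore not a chance level for them. Across the types, antagomiR-22-3p against the control mimic called 73 genes and the miR-127 mimic against the control antagomiR 1418. Across all genes the contrast between the controls and that between the treated groups correlated at r = 0.21 and rho = 0.38. With both contrasts averaged, 1810 genes were called between the 4 mimic-type and the 4 antagomiR-type libraries, 1341 higher and 469 lower in the mimic type, a comparison added after the data were seen. RLE size factors gave 1351 higher and 469 lower, and library totals, which moved the median log2 fold change of all genes from -0.014 to -0.15, gave 974 higher and 2522 lower. Without control mimic replicate 1 the count was 1114, and without control mimic replicate 2 it was 947. The type of oligonucleotide, its concentration and any difference in handling between the 2 arms cannot be told apart in this design, because the labels give no batch and each arm holds 1 type.

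**Figure D3:**
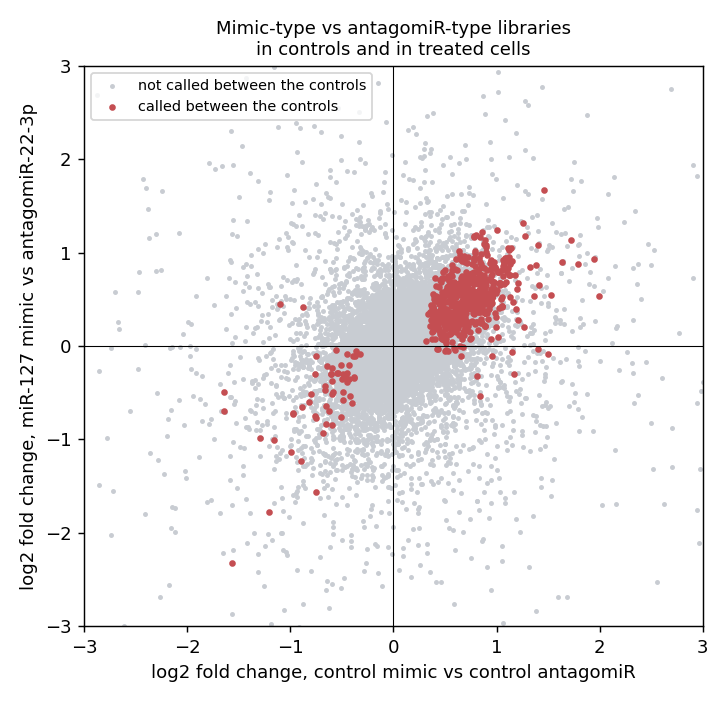
Log2 fold change of each gene between the control mimic and the control antagomiR (horizontal axis) and between the miR-127 mimic and antagomiR-22-3p (vertical axis); red points are the 722 genes called between the controls, and 180 genes, 1 of them called, lie outside the axes, which end at 3 in either direction. Of the red points 97.5% have the same sign on both axes.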

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

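The tests of explanations in this part were chosen after the result was seen. One result was picked out because the 2 treatment effects differed by a test of the difference: ENSOARG00000018571, with a log2 difference of 6.96. Too few reads do not account for its low level after the miR-127 mimic, since the library with 0 counts would have held 742 counts at the level of the control mimic. Genes that are present in one library and nearly absent in another, whatever the group, remain a possible explanation. There were 4 other genes with at least 5 CPM in 1 library and at most 0.15 CPM in another. In all 4, the 2 libraries of some group differed by over 10 times, which picking genes for a library near 0 favours. ENSOARG00000018571 did so too, with 0 and 36 counts (0 and 1.29 CPM of the unscaled totals) in the miR-127 mimic libraries. Both values lay under those of its control mimic libraries (21.2 and 22.8 CPM). In every library outside the miR-127 mimic group, ENSOARG00000018571 held between 21.2 and 93.0 CPM. One gene cannot decide between such presence or absence and an effect of the mimic. Whether its transcript holds a miR-127 site was not tested, because no sequence was used here.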

How the results depend on the processing

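The settings added after the data were seen were halved counts, 1 gene per matching set, library totals, the newer quasi-likelihood fit (legacy=FALSE) and the likelihood-ratio test. The planned legacy=TRUE fit is the default of the edgeR version used, so it is the main result itself. Its values could only stay the same, and they are among the recomputed values of the named genes counted below. For antagomiR-22-3p, with 0 genes called in the main test, DESeq2 called 58, the likelihood-ratio test 20, and no expression filter, only the 4 libraries compared, library totals and an adjusted p up to 0.1 called 1 each; leaving out single libraries gave 0 to 1. For the miR-127 mimic, also with 0, DESeq2 called 43, the likelihood-ratio test 92, library totals 17, no filter 6, an adjusted p up to 0.1 called 4, the replicate block 2, and only the 4 libraries compared, halved counts and legacy=FALSE called 1 each; leaving out single libraries gave 0 to 60, the highest without miR-127 mimic replicate 2. For the controls, with 722, DESeq2 called 1189 and the likelihood-ratio test 1270, and leaving out single libraries gave 2 to 966, with 2 to 336 when the library left out was a control; the other settings gave 678 to 1052. For the difference between the treatments, with 1, DESeq2 called 15, the likelihood-ratio test 37, no filter and library totals 2 each and the replicate block 0, and leaving out single libraries gave 0 to 103. For all mimic-type against all antagomiR-type libraries, with 1810, library totals called 3496, and leaving out single libraries gave 947 to 1910. The correlation of the 2 treatments' fold changes ran from -0.051 to 0.027 when single libraries were left out; it turned positive without control mimic replicate 1 (0.027) or antagomiR-22-3p replicate 1 (0.019), and stayed near 0. The replicate block moved no other count by over 1.5 times. The labels share only a number, and each treatment comparison holds 2 pairs, so what the number marks stays open. Of 312 recomputed values of the named genes that came with an adjusted p, none changed sign, 258 stayed on the same side of the threshold, 36 moved past it and 18 fell short of it; DESeq2 gave no adjusted p to the 4 genes named for antagomiR-22-3p. The cause of these changes was not tested, except that leaving out a library removes a replicate and an adjusted p up to 0.1 is a looser threshold; also asking for a fold of at least 2 left both treatment comparisons at 0. DESeq2 left 15218 of 16353 genes without an adjusted p for antagomiR-22-3p, 0 for the mimic and 1903 for the controls, and these count neither as called nor as lost. If both reads of a pair were counted, which was not settled, the number of independent fragments behind a count would be smaller than the count and the depth limits given would be too low; halved counts called 732 genes between the controls. The gene lists and the seed-site tests were not run under any setting.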

Other observations

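The tests in this part were chosen after the results were seen. The pattern weighed first is how reads were counted. At most 15.6% of counts from 1 to 100 were odd in any library, which is consistent with both reads of a pair being counted, and 84 pairs of genes had counts within 2% of each other in every library, against 0 in each of 20 permutations of one gene's libraries, which is consistent with the same reads being counted at more than 1 gene. These 80 genes, in 31 sets of up to 7, held between 5.32% and 8.02% of the counts of a library. In the control mimic against the control antagomiR, 57 of the 80 were called and all 57 were higher, in 20 of the 31 sets, where 10.4% of 4022 other abundant genes were called. The members of a set are not independent calls, and with 1 gene kept per set 678 genes were called between the controls.

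The second pattern is the distance between the 2 control groups. The signs go with a difference shared by the libraries of a type: with each contrast fitted in its own 4 libraries, 94.1% of the genes called between the controls kept their sign between the treated groups, against 65.5% of all genes. The counts are less even. AntagomiR-22-3p against the control mimic called 73 genes and the miR-127 mimic against the control antagomiR 1418, against 722 between the controls. Counts of calls do not measure the size of a difference, so they cannot decide whether it was the same in all groups. The contrast of the 2 treatment effects is also the contrast of the type difference in the controls with that in the treated cells. It called 1 of 16353 genes, which does not show that the sizes were equal. The count between the controls itself ran from 2 to 966 when single libraries were left out, so the size of the difference in each group stays open. Scaling does not account for the number of genes: with the control mimic libraries moved against the others by 1 factor, from -0.4 to 0.4 in log2, the lowest count was 592. With 1 gene kept per matching set 678 were left, but the sets hold only 57 of the 722 genes and reads shared by genes that do not match were not examined, so the part of reads counted at several genes stays open. Whether scaling lies behind the excess of higher genes stays open. Their share was 91.8% with TMM, 91.9% with RLE size factors and 47.6% with library totals, and any such factor moves all genes alike, so the share follows from the factor chosen. In a model with the type alone, the real split of the 8 libraries called 1750 genes, the highest of the other splits called 0, and 1 of the 35 splits, the real one, reached that count. Only 3 of the splits keep the 4 groups whole, too few for a share under 0.05. Every other split also mixes both types on each side, so a difference between the types would widen its residual spread and lower its calls. The splits therefore cannot decide whether the real count arose by chance. What also stays open, and untested, is whether the type of oligonucleotide, its concentration, or a difference in culture, day or sequencing between the 2 arms lies behind the distance.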
